A study of Mus musculus with 4 samples.

How the data were processed

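RNA was measured by sequencing in 4 libraries of tongue-derived epithelial cells from C57BL/6 mice, 2 labelled wild type and 2 labelled as a systemic knockout of Otub2, a deubiquitinase of the OTU family. Cells were grown in RPMI-1640 with 10% serum and RNA was extracted with TRIzol, per the labels' protocols. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

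The deposited table gives a raw read count for each gene in each library, per the file headers, and these counts are whole numbers. The authors also deposited an FPKM value for each count, per the file headers. Each FPKM equals the count divided by a gene length and by the total count of its own column, with a largest relative error of 9.3e-15 among genes with over 200 counts in both libraries compared. The submitters' processing notes name HISAT2, DESeq and the build GRCh38, with no version or role. GRCh38 is a human build, whereas the gene IDs are mouse Ensembl IDs. Of 54446 such IDs, 54409 were found in GENCODE mouse release 21 (GRCm38), which gave the coordinates and gene types used here. The counting tool, its strand setting, the annotation release and the handling of reads that map to several genes are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense pairs are therefore uncertain.

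The count columns of the knockout libraries are headed OE with the numbers 3 and 4, while the sample titles say KO with the same numbers. OE is a common abbreviation of overexpression, and under that reading every fold change given here would concern a gain of Otub2 and not its loss. Otub2 was at 19 and 24 CPM in these libraries and at 27.5 and 26.9 CPM in the controls (log2 fold change -0.34, 95% interval -1.11 to 0.43), which argues against a gain of its transcript. The titles and genotype labels were followed. They were assigned by the number, which no other title carries, and the libraries are called "labelled Otub2 knockout" throughout. The number of columns of per-sample values left unused was 0.

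The table also holds 14785 features without an Ensembl ID, symbol or description. They took 2.84% and 2.82% of the counts in the control libraries and 1.29% and 0.914% in the libraries labelled Otub2 knockout. They name no gene and were left out of library sizes and tests. The remaining gene counts summed to 12185345 and 11548186 in the controls and to 22719550 and 18911259 in the libraries labelled Otub2 knockout.

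Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM size factors, genes kept by filterByExpr, and Benjamini-Hochberg adjustment at 0.05 over the 21916 genes tested. Standard errors of log2 fold changes were taken from the F statistic, and intervals are 95% intervals on the same degrees of freedom. CPM values use the TMM-scaled library size. All fold changes are libraries labelled Otub2 knockout over controls. The 36 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and adjusted over the 36 lists. The correlation was also estimated from the residuals, and fry and cameraPR were run. Camera compares a list with all other genes tested, whereas fry asks whether the genes of a list move, on balance, one way.

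These lists covered MHC class I presentation, basal and differentiating keratinocytes, the cornified envelope, phospholipid, cholesterol and fatty acid synthesis, YAP and TAZ targets, NF-kB targets, mitosis, DNA replication, p53 targets, epithelial-mesenchymal transition, epithelial junctions, glycolysis, hypoxia, nuclear and mitochondrial genes of oxidative phosphorylation, the unfolded protein response, NRF2 targets, OTU deubiquitinases, ribosomal proteins, immediate early genes, histones, and markers of fibroblasts, skeletal muscle, smooth muscle and pericytes, endothelium, macrophages and dendritic cells, lymphocytes, neutrophils, Schwann cells and neurons, melanocytes, salivary and simple epithelium, and taste receptor cells. Symbols that the file gives under an older name were matched through the synonyms of a gene table. The lists, the groups, the tests, the alternatives and the rule for named genes were fixed before the data were examined, apart from those named here as added.

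The rule named 5 genes the study is known to concern, among them Otub2, Calml3, Ptdss1 and Ptdss2; 1 of the 5, 1 of the 36 lists and some list members are not reported here. It then named up to 10 genes per direction among those past the threshold, with both libraries labelled Otub2 knockout beyond both controls and a mean CPM of at least 5, without predicted genes, genes of chromosome Y or Xist. If none passed, it named the 5 with the smallest p in each direction, as not past the threshold. In each list it allowed up to 4 tested members with the smallest p. Members called when adjusted over a list alone are named as well, a choice made after their values were seen, as are the genes of the closing families and the transcripts of glands, heart and sex chromosomes.

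Alternatives were RLE, upper-quartile and library-size-only scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a mean CPM of at least 5, limma-trend on log2(FPKM + 1), a minimum log2 fold change of 1, glmTreat at 1.5-fold, and each library left out in turn. With a library left out, the lone library of its group was assumed to vary like the pair of the other group. Chosen after seeing the data were robust dispersion estimates, keeping the unannotated features, and a fit without 371 genes that lay more than 16 times higher in the library labelled Otub2 knockout 3 than in each other library. Marker lists of cardiomyocytes and salivary secretory cells were also added after seeing the data. Each library labelled Otub2 knockout was further set alone against the controls.

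The tests were tried on simulated counts with the means, library sizes and dispersions of the 4 libraries and 200 genes changed by known folds. Among 21916 genes, edgeR recovered 0% of 67 genes changed 2-fold, 8.96% of 67 changed 4-fold and 89.4% of 66 changed 16-fold, with 5 false calls. DESeq2 recovered 0%, 44.8% and 100%, with 81 false calls, and voom 0%, 4.48% and 68.2%, with 2 false calls. Without the library labelled Otub2 knockout 3, among 23181 genes, edgeR recovered 37.3%, 97% and 100%, with 6 false calls. In that setting every simulated library took its spread from the controls alone, so its recovery holds only if the lone library varies as little. With all 4 libraries, camera with the preset correlation found a simulated list of 30 genes moved 2-fold (adjusted p = 2.46e-09). It also called a list that had not been moved (adjusted p = 0.0411). With an estimated correlation the adjusted p-values were 0.0407 for the moved list and 0.321 for the other.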

Results

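To ask how loss of Otub2 alters gene expression in tongue epithelium, transcript counts of 4 libraries were compared, 2 from wild-type cells (Control 1 and 2) and 2 from cells labelled Otub2 knockout (3 and 4). Total counts were 12541345 and 11882900 in the controls and 23017183 and 19085713 in the libraries labelled Otub2 knockout. At least 10 counts were found for 21618 and 20972 genes in the controls and for 18990 and 18492 genes in the others. Across the genes tested, log2 CPM of the controls correlated at r = 0.983, that of the pair labelled Otub2 knockout at 0.901, and pairs of a control with the library labelled Otub2 knockout 3 or 4 at 0.883 and 0.886 or at 0.932 and 0.938. These correlations are across genes, which are not independent replicates. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of 14.5 between the controls and 737 between the libraries labelled Otub2 knockout), so none was counted as a duplicate.

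The library labelled Otub2 knockout 3 stood apart in its most abundant transcripts. Its 10 most abundant genes took 40% of its gene counts, against 12.4% and 12% in the controls and 8.12% in the library labelled Otub2 knockout 4. In this library 12 genes of salivary secretory cells held 35.9% of gene counts, against 0.0014% and 0.00111% in the controls and 0.00326% in the other library labelled Otub2 knockout. Mucl2, a secreted mucin-like protein, had 5462635 counts there and 21, 16 and 348 in Control 1, Control 2 and the library labelled Otub2 knockout 4. A set of 20 cardiomyocyte genes held 1.94% of its counts, against 0.0106%, 0.011% and 0.00886% in the same 3 libraries, and Myh6, the cardiac alpha myosin heavy chain, had 134463 counts against 53, 60 and 9. Both sets, and Mucl2 and Myh6 as examples, were chosen after their values were seen.

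**Figure D1:**
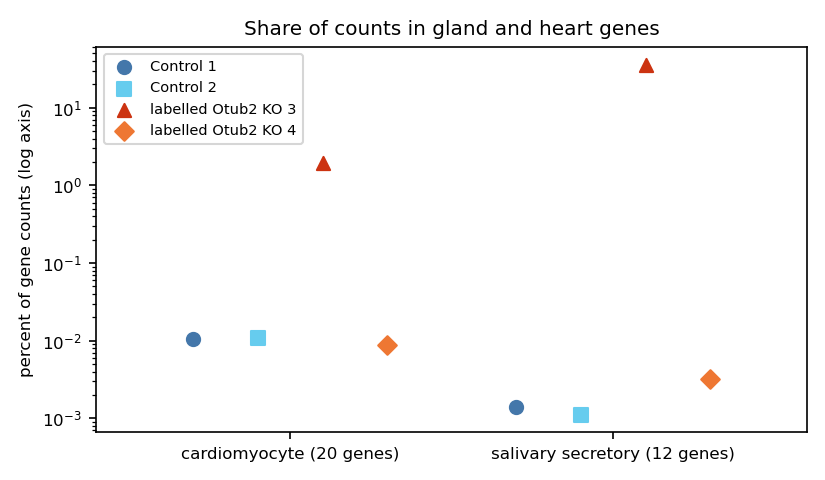
Share of gene counts (percent, log axis) taken by 20 cardiomyocyte genes and 12 salivary secretory genes in each of the 4 libraries, 1 point per library. The library labelled Otub2 knockout 3 lies at 1.94% and 35.9%, and the other 3 libraries lie at or below 0.011%.

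Otub2 transcripts were present in all 4 libraries. Otub2 (ENSMUSG00000021203, protein coding, chromosome 12, 103388682 to 103406350, plus strand, GRCm38) had 393 and 367 counts in the controls and 272 and 495 in the libraries labelled Otub2 knockout. The TMM-scaled levels were 27.5 and 26.9 CPM in the controls and 19 and 24 CPM in the others, a log2 fold change of -0.34 (SE 0.302, 95% interval -1.11 to 0.43, n = 2 libraries per group, edgeR adjusted p = 0.485). The difference did not pass the test. The labels do not give the part of the gene that was deleted, and a gene-level count can include reads from the remaining exons, so these values do not check a deletion. Both libraries lay below both controls, the opposite of what a gain of the transcript would give.

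Among genes the study is known to concern, Calml3 was lower in both libraries labelled Otub2 knockout than in both controls. Calml3 (ENSMUSG00000063130, chromosome 13, 3802896 to 3804316, minus strand), a calmodulin-like protein of differentiating epithelium, was at 896 and 662 CPM in the controls and at 278 and 199 CPM in the libraries labelled Otub2 knockout (log2 fold change -1.71, SE 0.353, edgeR adjusted p = 0.166). The phosphatidylserine synthases Ptdss1 and Ptdss2 had log2 fold changes of -0.17 (SE 0.238, adjusted p = 0.649) and 0.38 (SE 0.357, adjusted p = 0.504). None of these genes passed the edgeR test. With DESeq2 Calml3 passed (log2 fold change -1.47, adjusted p = 0.0241), and over all settings its adjusted p ran from 7.56e-10 to 0.832. If the study picked Calml3 from these libraries, its direction here is not independent evidence.

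Several genes of matrix remodelling, patterning and epithelial identity lay far from the controls in both libraries labelled Otub2 knockout. Mmp10, a stromelysin that degrades extracellular matrix, was at 3.50 and 3.22 CPM in the controls and at 46.3 and 52.7 CPM in the others (log2 fold change 3.88, SE 0.322). Krt7, a keratin of simple epithelia, was at 0.98 and 0.513 CPM against 27.3 and 16.2 CPM (4.85, SE 0.596). Cyr61, a matricellular protein, Foxc1, a forkhead transcription factor, and Meis1, a homeobox transcription factor, had log2 fold changes of 2.54, 2.64 and 2.30 (SE 0.277, 0.297 and 0.267). In the other direction, the casein gene Csn1s1 was at 357 and 437 CPM in the controls and at 6.15 and 7.84 CPM in the others (-5.83, SE 0.352). Isl1, a LIM homeobox transcription factor, was at 59.6 and 50.8 CPM against 1.12 and 2.47 CPM (-4.92, SE 0.506). The serpin Serpinb3a, the secreted epithelial protein Slurp1 and the hard keratin Krt32 had log2 fold changes of -3.45, -3.23 and -4.15 (SE 0.362, 0.375 and 0.504). The edgeR adjusted p was 0.162 for Csn1s1 and 0.166 for each of the other 9.

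None of these genes passed the threshold in edgeR, where 0 genes were called higher and 0 lower among 21916 (smallest adjusted p 0.162), with 2064 higher and 3325 lower at an unadjusted p under 0.05. Voom called 0 and 0, and DESeq2 called 1135 higher and 129 lower, the 10 genes above among them, with adjusted p-values from 1.2e-25 for Csn1s1 to 1.39e-05 for Meis1. Over all settings the adjusted p of Csn1s1 ran from 5.56e-53 to 0.832 and that of Meis1 from 1.26e-15 to 0.832. Without the library labelled Otub2 knockout 3, edgeR called 4359 genes higher and 5097 lower, and without the library labelled Otub2 knockout 4 it called 5243 and 2961. In those fits the lone library is assumed to vary as little as the 2 controls do.

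**Figure D2:**
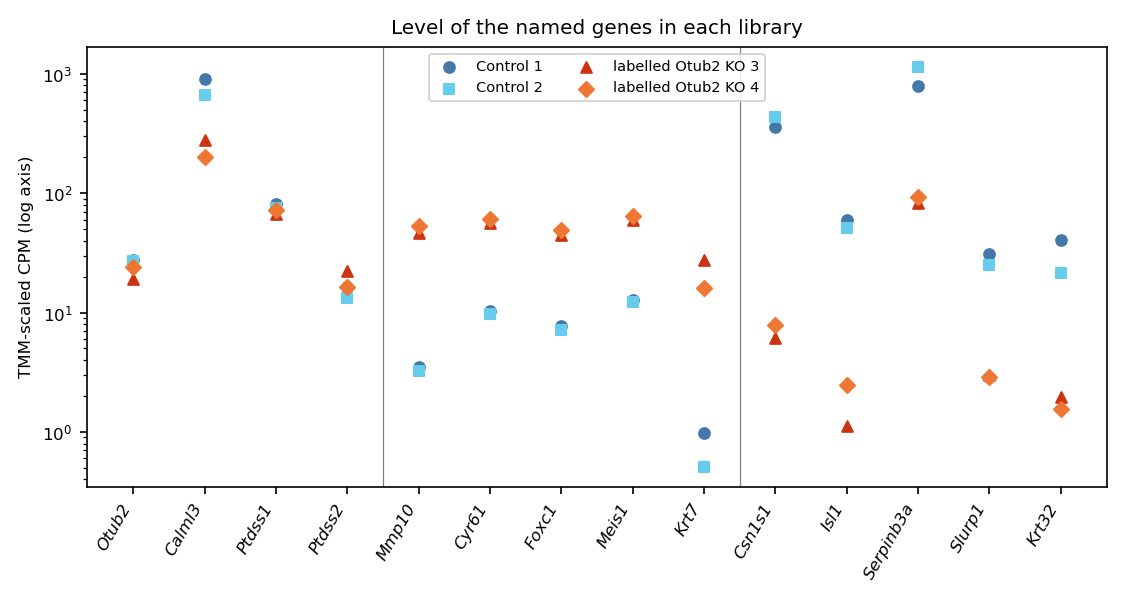
TMM-scaled level (CPM, log axis) of 4 genes of the study and of the 5 genes with the smallest p in each direction, 1 point per library. Otub2 lies between 19 and 27.5 CPM in all 4 libraries, and Csn1s1 lies at 357 and 437 CPM in the controls and at 6.15 and 7.84 CPM in the libraries labelled Otub2 knockout.

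Of 11788 genes with a mean CPM of at least 5, both libraries labelled Otub2 knockout lay at least 2-fold above both controls in 450 and at least 2-fold below in 177 on the TMM scale. Counting any size of difference, both lay above in 5038 (42.7%) and below in 1410 (12%), where chance gives 16.7% in each direction. This balance depended on the scaling. With upper-quartile scaling 16.1% lay above and 30.8% below, with library size only 13.7% and 21.1%, and with each library centred on its own median 23.1% and 23.7%. The counts at 2-fold turned to 139 above and 467 below, 172 and 354, and 184 and 346 under these 3 scalings.

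To see which differences appeared in each library labelled Otub2 knockout, each was set alone against the controls. Among the 22911 genes tested in both fits, library 3 had 4827 genes higher and 2961 lower, and library 4 had 4277 higher and 5097 lower. Of these, 1759 were higher in both and 1878 lower in both, while 652 were called in opposite directions. Independent lists of these sizes would share 901 and 659 genes. The controls are too few to be split, so part of the excess over 901 and 659 may come from the shared controls.

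The gene lists gave a broader view, and 16 of 36 were called by camera with the preset correlation, 12 higher and 4 lower than other genes. None was called with an estimated correlation (smallest adjusted p = 0.781) or by fry (smallest adjusted p = 0.225), and fry's mixed test, which asks for change in either direction, called 16. No member of any list passed the edgeR test over all genes. For each called list the count of members adjusted over the list alone is given with it. On the TMM scale 42.7% of all genes with a mean CPM of at least 5 lay above both controls and 12% below. A list count near these shares does not by itself show a change. Camera compares each list with all other genes tested, including those of low abundance. Genes at 0.5 to 1 CPM had a median log2 fold change of -1.12, and those at 10 to 50 CPM of 0.47.

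Genes of keratinocyte differentiation were lower in both libraries labelled Otub2 knockout. Of 30 tested genes of differentiating oral keratinocytes, 21 lay below both controls in both libraries and 3 above, and the median log2 difference from the controls was -1.18 in library 3 and -0.94 in library 4, against 0.12 between the controls. Krtdap, a secreted protein of differentiating keratinocytes, was at 1360 and 1500 CPM in the controls and at 497 and 537 CPM in the others. The ammonium transporter Rhcg was at 1.82 and 2.12 CPM in the controls and 0.279 and 0.194 CPM in the others. Its log2 fold change was -3.04 (SE 0.502), and it was the only member called when adjusted over the list alone (1 of 30). Rhcg had 26 and 29 counts in the controls against 4 and 4. Genes at 1 to 2 CPM were lower as a whole, with a median log2 fold change of -0.70. Camera called the list lower (adjusted p = 0.000512; adjusted p = 0.781 with an estimated correlation). The call was lost without library 3 (adjusted p = 0.122) and with unannotated features kept (adjusted p = 0.0725), and over all settings its adjusted p ran from 1.5e-08 to 0.781. Calml3 belongs to this list. Library 3 holds the gland and heart transcripts, and fibroblast and smooth muscle markers were higher in the main comparison. A difference in cell composition was not separated from the change in these differentiation genes.

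The basal and cornified layers did not form such a block. In the cornified envelope list 10 of 34 genes lay below both controls and 3 above. Loricrin (Lor), the main envelope protein, was at 1900 and 1640 CPM in the controls and at 564 and 452 CPM in the others (log2 fold change -1.80, SE 0.349, adjusted p = 0.166). The list was not called (adjusted p = 0.446), and its median of -0.36 and mean of 0.03 differ in sign. Among 25 basal keratinocyte genes 8 lay above both controls and 7 below (adjusted p = 0.182). In both lists the libraries went opposite ways by the median log2 difference from the controls. It was -0.75 in library 3 and 0.23 in library 4 for the envelope genes, and -0.31 and 0.87 for the basal genes. Lama3, a laminin chain that anchors basal cells, had a log2 fold change of 2.40 (SE 0.516). Of 32 genes of epithelial junctions 12 lay above and 7 below (adjusted p = 0.0714), and Cldn3, a tight junction claudin, was the only member called over the list alone, at 0.56 and 0.806 CPM in the controls and 28.8 and 9.73 CPM in the others.

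Targets of YAP and TAZ, the transcriptional effectors of the Hippo pathway, were higher. Of 24 genes 14 lay above both controls in both libraries and 1 below, with a median log2 fold change of 0.64. Adjusted over the list alone, 5 rose (Amotl2, Arhgef17, Cyr61, Nt5e and Tead1) and 0 fell. Tead1, the DNA-binding partner of YAP, was at 36.0 and 32.4 CPM in the controls and at 78.7 and 91.6 CPM in the others (log2 fold change 1.32, SE 0.251). Camera gave adjusted p = 0.000545, and adjusted p = 0.781 with an estimated correlation. With only genes of mean CPM at least 5, camera's adjusted p for this list was 0.0234. Fibroblast and smooth muscle markers were higher as well (median log2 fold changes 1.5 and 1.36), mainly in library 3. Their median differences from the controls were 1.61 and 1.77 in library 3 and 0.49 and 0.349 in library 4. For the YAP and TAZ targets the median was 0.596 in library 3 and 0.953 in library 4. A difference in cell composition was not separated from the change in these targets.

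Genes of epithelial-mesenchymal transition and of fibroblasts were also higher than other genes tested. Of 27 transition genes 13 lay above both controls and 3 below, near the shares of 42.7% and 12% among genes of mean CPM at least 5. Adjusted over the list alone, 6 rose, among them Acta2, Fn1, Mmp3, Postn and Tnc. Mmp3, another stromelysin, was at 16.1 and 18.5 CPM in the controls and at 63.1 and 43.5 CPM in the others. The list was called (adjusted p = 0.00132; adjusted p = 0.781 with an estimated correlation). With only genes of mean CPM at least 5, camera gave it an adjusted p of 0.035. The median difference of the transition list from the controls was 0.575 in library 3 and 0.531 in library 4. Genes at 10 to 50 CPM had medians of 0.37 and 0.41. Of 24 fibroblast markers 13 lay above and 0 below, and 8 rose when adjusted over the list alone (Col1a1, Col1a2, Col3a1, Col5a1, Col5a2, Col6a1, Fbln2 and Postn). Collagen genes Col1a1 and Col1a2 had log2 fold changes of 1.54 (SE 0.309) and 1.34 (SE 0.254), and the matrix protein Fbln2 of 2.17 (SE 0.388). This list was called too (adjusted p = 4.99e-05; adjusted p = 0.781 with an estimated correlation). Its median difference from the controls was 1.61 in library 3, which holds the gland and heart transcripts, and 0.49 in library 4. The transition and fibroblast lists share 3 genes, and 18 of 25 fibroblast markers had a mean of at least 5 CPM in the controls.

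Genes of cell division were higher mainly in library 4, and the difference between the 2 libraries was not tested. The median log2 difference from the controls over 37 mitotic genes was 1.74 in library 4 and 0.05 in library 3, and over 42 DNA replication genes it was 1.51 and -0.21. The mitotic kinase Aurka was at 11.9 and 13.5 CPM in the controls, 18.6 CPM in library 3 and 35.4 CPM in library 4, and Pola1, the catalytic subunit of polymerase alpha, at 9.73, 14.7, 21.8 and 43.1 CPM. In both libraries 13 of the 37 mitotic and 6 of the 42 replication genes lay above both controls. Both lists were called (adjusted p = 4.99e-05 and 0.000545; adjusted p = 0.81 and 0.844 with an estimated correlation), and 0 members of either passed when adjusted over the list alone. Without library 4 neither was called (adjusted p = 0.865 and 0.178), and the direction of the DNA replication list reversed. The replication call was also lost with the mean CPM filter (adjusted p = 0.0911). Over all settings the adjusted p of the mitotic list ran from 1.52e-16 to 0.865 and that of the replication list from 1.27e-16 to 0.844.

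Hypoxia, glycolysis and unfolded protein response genes were higher than other genes tested. With the mean CPM filter camera's adjusted p was 0.0136 for hypoxia, 0.0471 for glycolysis and 0.00108 for the unfolded protein response. The glycolysis median was 0.39 in library 3 and 0.80 in library 4, against 0.37 and 0.41 for genes at 10 to 50 CPM. In the hypoxia list 16 of 20 genes lay above both controls and 1 below (median log2 fold change 0.94). P4ha1, a collagen prolyl hydroxylase, was called over the list alone (1 of 20) at 25.9 and 28.2 CPM in the controls and 66.9 and 88.7 CPM in the others, and Bnip3, a mitophagy receptor, was at 24.9 and 36.7 CPM against 65.2 and 97.6 CPM. Camera gave adjusted p = 8.74e-05 for this list (adjusted p = 0.804 with an estimated correlation). In the glycolysis list 12 of 21 lay above and 0 below (adjusted p = 0.00132; adjusted p = 0.804 with an estimated correlation), with 0 members called over the list alone and 5 at an unadjusted p under 0.05. The lactate transporter Slc16a3 was at 12.7 and 22.7 CPM in the controls, 33.1 CPM in library 3 and 142 CPM in library 4. Without library 4 the glycolysis call was lost (adjusted p = 0.231; range over all settings 2.14e-06 to 0.804). Of 25 unfolded protein response genes 21 lay above both controls and 1 below, with medians of 0.73 in library 3 and 0.79 in library 4 (adjusted p = 1.52e-05; adjusted p = 0.781 with an estimated correlation). None of them was called over the list alone, and 14 had an unadjusted p under 0.05. Atf3 and Chac1, induced in the integrated stress response, had log2 fold changes of 1.72 (SE 0.407) and 1.79 (SE 0.508).

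Mitochondrial transcripts differed mainly in library 3, which also holds the heart transcripts, and the difference between libraries 3 and 4 was not tested. Nuclear genes of oxidative phosphorylation had a median log2 difference from the controls of 1.33 in library 3 and 0.11 in library 4, with 17 of 44 above both controls and 1 below. Sdha, the catalytic subunit of succinate dehydrogenase, was at 87.1 and 105 CPM in the controls, 434 CPM in library 3 and 167 CPM in library 4. This list was called (adjusted p = 4.99e-05; adjusted p = 0.81 with an estimated correlation), with 0 members called over the list alone and 7 at an unadjusted p under 0.05. With the mean CPM filter camera gave it an adjusted p of 0.0453. The call was lost without library 3 (adjusted p = 0.0886; range over all settings 5.95e-10 to 0.81). The 14 mitochondrially encoded genes had medians of 3.15 in library 3 and -0.70 in library 4 and were not called (adjusted p = 0.0511). The complex I subunit mt-Nd5 was at 111 and 171 CPM in the controls, 6250 CPM in library 3 and 146 CPM in library 4.

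In lipid synthesis the phospholipid list was called, narrowly. Of 32 genes of phosphatidylserine and phospholipid synthesis 12 lay above both controls and 3 below, with a median log2 fold change of 0.27, lower than the 0.41 of all genes with a mean CPM of at least 5. Chka, the choline kinase that begins phosphatidylcholine synthesis, and Cds2, a CDP-diacylglycerol synthase, had log2 fold changes of 1.25 (SE 0.326) and 1.32 (SE 0.353). The list was called (adjusted p = 0.0398; adjusted p = 0.781 with an estimated correlation), with 0 members called over the list alone and 6 at an unadjusted p under 0.05. The call was lost with the mean CPM filter (adjusted p = 0.915), upper-quartile scaling (adjusted p = 0.096) and library size only (adjusted p = 0.0537), without library 4 (adjusted p = 0.15), without Control 2 (adjusted p = 0.0577) and without the genes of library 3 alone (adjusted p = 0.091). Over all settings the adjusted p ran from 9.43e-05 to 0.915. The median turned to -0.20 with upper-quartile scaling, -0.18 with library size only and -0.17 on log2(FPKM + 1). The median of all genes shifted by -0.466, -0.458 and -0.435 under these settings, so the turn is not particular to this list. Neither cholesterol synthesis (25 genes, adjusted p = 0.776) nor fatty acid synthesis (21 genes, adjusted p = 0.275) was called. The acetoacetyl-CoA thiolase Acat2 had a log2 fold change of -0.89 (SE 0.287) and the long-chain acyl-CoA synthetase Acsl4 of 1.54 (SE 0.406).

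The 18 genes of MHC class I presentation (adjusted p = 0.551, median 0.18, mean -0.02), the 33 NF-kB targets (adjusted p = 0.432) and the 26 p53 targets (adjusted p = 0.189) were not called. H2-T23, Nfkb2 and Phlda3, the members with the smallest p, had log2 fold changes of 0.58, 1.12 and -0.92 (SE 0.301, 0.329 and 0.314).

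Ribosomal protein genes were lower in both libraries labelled Otub2 knockout. Of 47 genes 41 lay below both controls in both libraries and 0 above, with median log2 differences of -0.80 in library 3 and -0.54 in library 4 against -0.13 between the controls. Rpl30 was at 592 and 623 CPM in the controls and at 207 and 264 CPM in the others, and Rps20 at 1300 and 1230 CPM against 524 and 569 CPM. This was the list with the smallest camera p (adjusted p = 9.18e-06; adjusted p = 0.81 with an estimated correlation), with 0 members called over the list alone and 11 at an unadjusted p under 0.05. The call was lost with unannotated features kept (adjusted p = 0.0578).

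NRF2 targets, OTU deubiquitinases, immediate early genes and histones were not called (adjusted p = 0.24, 0.152, 0.159 and 0.0816 for 29, 15, 26 and 15 genes). Of the NRF2 targets 15 lay below both controls and 2 above, and Txnrd1, a thioredoxin reductase, was the only member called over the list alone, with a log2 fold change of 1.5 (SE 0.245). Among OTU deubiquitinases Otud7a was the only member called over the list alone, at 10.7 and 11.4 CPM in the controls and 2.16 and 2.42 CPM in the others. The nuclear receptor Nr4a1, an immediate early gene, was at 8.47 and 8.13 CPM against 83.4 and 31.6 CPM. The linker histone gene Hist1h1c, also the only member called over its list alone, had a log2 fold change of 2.06 (SE 0.288).

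Among markers of other cells, those of salivary and simple epithelium and of smooth muscle and pericytes were higher mainly in library 3. The salivary and simple epithelium list was called higher (15 genes, adjusted p = 0.000512; adjusted p = 0.804 with an estimated correlation), with a median log2 difference of 5.03 in library 3 and -0.25 in library 4, and without library 3 the call was lost (adjusted p = 0.194; range over all settings 1.9e-08 to 0.804). In the controls 1 of its 19 genes reached a mean of 5 CPM. Adjusted over the list alone, 2 members rose, Krt7 and the secreted gland protein Bpifa2, the latter at 0.56 and 0.732 CPM in the controls and 12.5 and 7.31 CPM in the others. Smooth muscle and pericyte markers gave medians of 1.77 and 0.35 (12 genes, adjusted p = 0.0398; adjusted p = 0.804 with an estimated correlation), and the call was lost without library 3 (adjusted p = 0.226) and with the mean CPM filter (adjusted p = 0.171), among others, with a range over all settings of 0.000653 to 0.804. In the controls 6 of the 13 smooth muscle and pericyte genes reached a mean of 5 CPM. Acta2, smooth muscle actin, was the only member called over that list alone, at 5.25 and 7.40 CPM in the controls and 120 and 31.2 CPM in the others.

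Lymphocyte markers were lower, and 16 of 22 lay below both controls and 0 above. Their median log2 difference was -1.29 in library 3 and -1.64 in library 4, against -0.41 between the controls. Adjusted over the list alone, 7 fell, among them Cd2, Cd3d, Cd3g, Cd79b, Il7r and Ptprcap. Their levels were low, and Cd3d, a chain of the T cell receptor complex, was at 1.96 and 1.46 CPM in the controls and 0.349 and 0.29 CPM in the others. Only 4 of the 24 markers reached a mean of 5 CPM in the controls. The list was called (adjusted p = 1.58e-05; adjusted p = 0.781 with an estimated correlation). Genes of such low abundance were lower as a whole, with a median log2 fold change of -1.12 over 3641 genes at 0.5 to 1 CPM and of 0.47 over 6022 genes at 10 to 50 CPM. Neutrophil markers were called lower as well (12 genes, median -1.05, adjusted p = 0.0425; adjusted p = 0.804 with an estimated correlation), with 0 members called over the list alone and 4 at an unadjusted p under 0.05. That call was lost without library 3 (adjusted p = 0.213), without Control 1 (adjusted p = 0.0804) and with unannotated features kept (adjusted p = 0.301), among others, with a range over all settings of 0.00483 to 0.804. In the controls 7 of its 15 genes reached a mean of 5 CPM, and 5 belong to another list as well. It includes S100a8, which keratinocytes also express, at 760 and 706 CPM in the controls and 204 and 292 CPM in the others.

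The remaining cell lists were not called. Adjusted p was 0.0815 for 20 endothelial genes, 0.148 for 25 macrophage and dendritic genes, 0.875 for 21 skeletal muscle genes, 0.75 for 13 Schwann cell and neuron genes, 0.678 for 5 melanocyte genes and 0.223 for 11 taste receptor cell genes. Endothelial genes had medians of 1.35 in library 3 and -0.35 in library 4. Adjusted over the skeletal muscle list alone, the skeletal actin gene Acta1 rose, at 1.61 and 0.952 CPM in the controls and 130 and 18.4 CPM in the others, and the parvalbumin gene Pvalb fell, with 8 and 8 counts against 0 and 0. The skeletal muscle list had a positive median and mean (0.68 and 1.55) although camera placed it on the lower side, and the Schwann cell and neuron list had a median of -0.08 and a mean of 0.03.

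**Figure D3:**
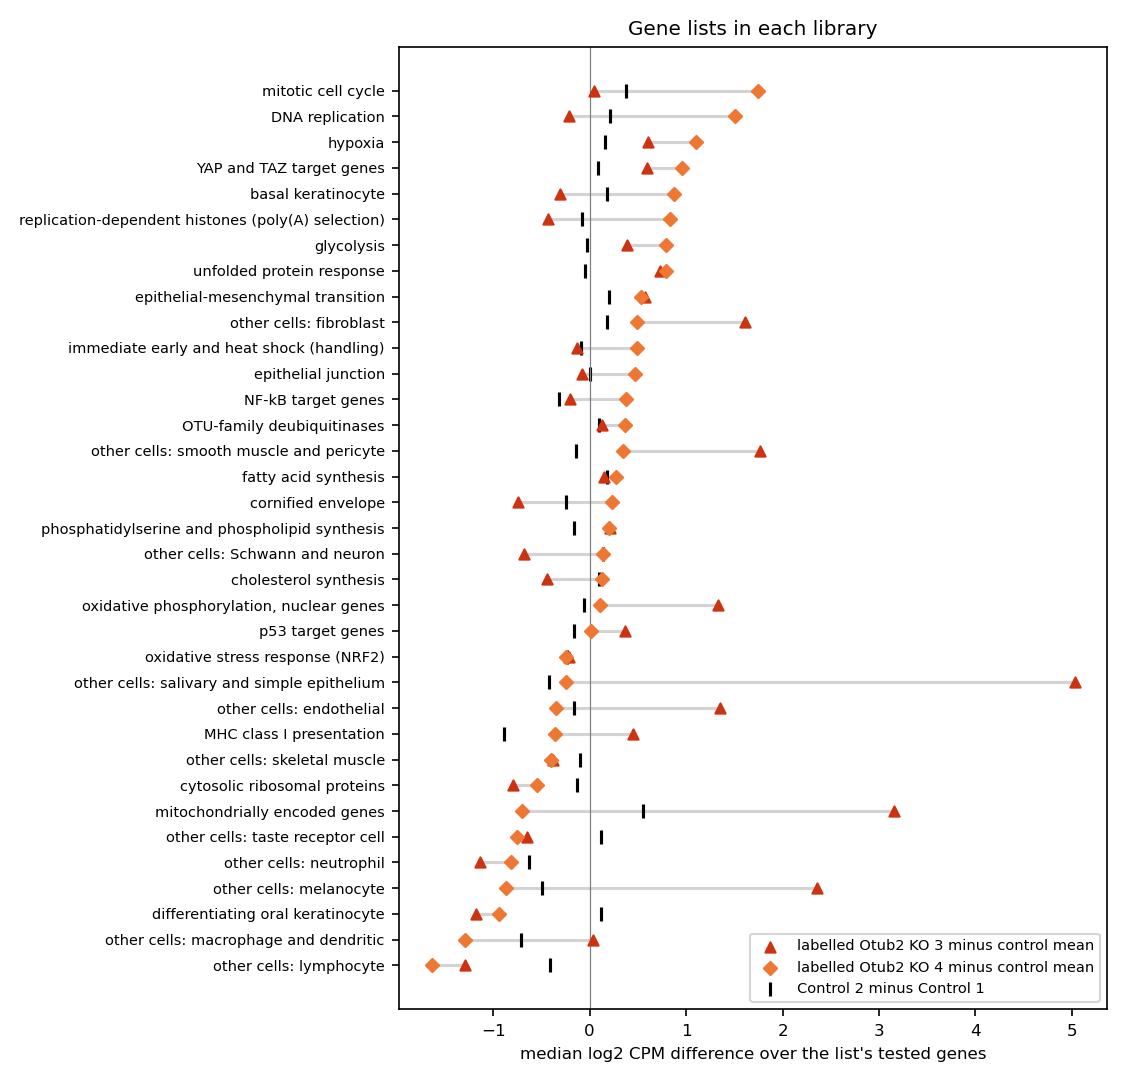
Median log2 CPM difference over the tested genes of each of 35 lists, for the libraries labelled Otub2 knockout 3 and 4 against the control mean, with the difference between the 2 controls as a bar. The lists of ribosomal proteins (-0.80 and -0.54) and the unfolded protein response (0.73 and 0.79) lie close together in both libraries, and salivary and simple epithelium (5.03 and -0.25) and mitotic genes (0.05 and 1.74) lie far apart.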

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

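The count of unannotated features was chosen after the data were seen. Among 123 features without an Ensembl ID and with a mean CPM of at least 5, 10 lay at least 2-fold above both controls in both libraries labelled Otub2 knockout and 11 lay at least 2-fold below. They stand out because the comparisons of the report do not use these features. None reached an adjusted p under 0.05 in edgeR (0 features), and they name no gene.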

How the results depend on the processing

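The settings with robust dispersions, with unannotated features kept, and without the 371 genes of library 3 alone were chosen after seeing the data. Otub2 kept its direction and missed the threshold under all 15 settings, with log2 fold changes from -0.81 to -0.08. The count of 0 genes higher and 0 lower held under RLE and upper-quartile scaling, voom, the mean CPM filter and the 3 added settings. Both fold minimums gave 0 too, as they can only remove calls. It became 37 and 1433 with library size only, 1135 and 129 with DESeq2, 6 and 3 without a filter on low counts, and 50 and 2864 on log2(FPKM + 1), and ran from 0 to 5243 and from 0 to 5097 when a library was left out. The count was 0 without either control and rose without either library labelled Otub2 knockout, when the spread comes from the controls alone. For the other changes the cause was not tested. DESeq2 left 32146 of 47373 adjusted p-values undefined. Against TMM the median of all genes shifted by -0.47 with upper-quartile scaling, -0.46 with library size only, 0.24 with DESeq2, -0.32 with the mean CPM filter, 0.13 without a filter, -0.43 on log2(FPKM + 1) and 0.26 with unannotated features kept.

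The 16 called lists became 0 with an estimated correlation, 0 by fry and 26 without a filter on low counts, with 17 to 20 when a library was left out. Of the 16, the mean CPM filter kept 11, leaving out library 3 kept 11, and leaving out library 4 kept 12, while the DNA replication list reversed there (adjusted p = 0.178, with 1.27e-16 the lowest when a library was left out). Among named genes Ptdss1 reversed with DESeq2 (0.0818) and with unannotated features kept (0.0832), and Ptdss2 with upper-quartile scaling (-0.0885), library size only (-0.11) and log2(FPKM + 1) (-0.0754). The cause was not tested. Of 83 genes other than Otub2 named for the comparison, the lists or the families, DESeq2 brought 58 past the threshold in the same direction. Of the genes in the text, 37 were added after their values were seen. The family genes were named for their calls in each library alone, which are the fits without library 4 or library 3. Their passing in those fits was fixed by that choice and does not show that the results hold. No paired analysis was possible because the replicate numbers of the 2 groups (1 and 2 against 3 and 4) share none. In counts simulated at these depths edgeR recovered 0% of genes changed 2-fold with both libraries labelled Otub2 knockout. Without library 3 every simulated library was given the spread of the controls. Recovery in that setting therefore does not show a gain of power in these data.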

Other observations

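All tests of explanations in this part, and the gene families, were chosen after the results were seen. Gene families outside the lists were counted with calls from each library labelled Otub2 knockout alone against the shared controls, where 7.68% of the genes tested in both were called higher in both and 8.20% lower in both. Of 11 laminin genes 7 were called higher in both libraries and 0 lower, and of 6 type IV collagen genes 4 were called higher and 0 lower. Lama5 was at 47.3 and 66.4 CPM in the controls and at 186 and 212 CPM in the libraries labelled Otub2 knockout, and Col4a6 at 0.28 and 0.439 CPM against 5.52 and 14.5 CPM. Of 5 Iroquois homeobox genes 4 were called higher in both, with Irx4 at 1.89 and 2.05 CPM against 37.8 and 15.9 CPM. Of 20 matrix metalloproteinase genes 5 were called higher in both (Mmp10, Mmp11, Mmp12, Mmp13 and Mmp3) and 1 lower (Mmp25).

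Keratins, clade B serpins and S100 genes had more genes called lower than higher. Of 39 keratin genes 11 were called lower in both libraries, Krt4, Krt13, Krt76 and Krt10 among them, and 5 higher (Krt7, Krt8, Krt18, Krt23 and Krt42). Keratins Krt7, Krt8 and Krt18 belong to simple epithelium, and library 3, which holds the gland transcripts, had the higher levels, with Krt8 at 0.21 and 0.806 CPM in the controls, 82.2 CPM in library 3 and 4.45 CPM in library 4. Krt10, the suprabasal keratin of cornifying epithelium, was at 840 and 1890 CPM in the controls and at 49.2 and 236 CPM in the others. Of 19 clade B serpins 8 were called lower and 1 higher, with Serpinb12 at 855 and 1180 CPM against 156 and 188 CPM, and of 12 S100 genes 4 were called lower and 0 higher. Late cornified envelope genes did not go with them, and of 15 tested 1 (Lce3e) was called higher and 0 lower, with median log2 differences from the controls of -0.15 in library 3 and 2.80 in library 4. In libraries 3 and 4 these medians were 1.37 and 1.39 for laminins, 1.73 and 0.89 for type IV collagens, 1.99 and 1.29 for Iroquois genes, -0.77 and -0.97 for keratins, -0.92 and -0.77 for clade B serpins and -1.20 and -0.13 for S100 genes. The median log2 fold changes of these families over both libraries kept their sign under the other scalings, and no test of the families as groups was run. None of these genes passed the edgeR test over all 4 libraries.

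Sex-linked transcripts also differed between the groups. Xist had 8 and 6 counts in the controls and 4444 and 3287 in the libraries labelled Otub2 knockout, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 64 and 68, 36 and 37, 20 and 15, and 9 and 20 counts in the controls against 558 and 606, 222 and 692, 126 and 313, and 73 and 131 in the others. These genes were chosen after their values were seen. The labels give neither the sex nor the number of the animals, so differences of animals or source between the groups are not separated from the genotype in any comparison here.

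The gland and heart transcripts of library 3 may come from RNA of heart and gland tissue in that library. All 20 of 20 cardiomyocyte markers lay at least 10-fold above the higher control there, but they were picked because they were high, so this does not test a mixed source, which stays open. The genotype would have to raise these genes in library 4 as well. There the median log2 difference from the controls was -0.264 for the heart genes (range -2.28 to 2.12, against at least 3.97 in library 3) and -0.197 for the 12 gland genes (range -0.721 to 3.25, against at least 6.75 in library 3), which argues against the genotype as the cause of the levels in library 3. In library 4, 2 of the 12 gland genes lay at least 10-fold above the higher control, Mucl2 (348 counts against 21 and 16) and Pip, which had 0 and 0 counts in the controls and 13 there and so has no measurable fold. Scgb2b27 (106 counts against 21 and 16) and Scgb1b27 (34 against 6 and 3) were also higher there, although the median of the 12 genes was -0.197. A smaller rise of Mucl2 and of these genes in library 4 stays open. In library 3 the basal keratinocyte list had a median ratio to the controls of 0.791 on the TMM scale (0.472 for Krt14). This argues against a tissue without such cells in place of tongue epithelium. The TMM factor was 0.65 for library 3 and 1.18 and 1.19 for the controls, so the ratio is not one of shares of counts. Whether gland tissue expresses these genes at such levels was not tested. Whether the RNA joined the sample in the cells, at extraction or in the library stays open.

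Genes of low abundance, the lymphocyte markers among them, were lower in both libraries labelled Otub2 knockout. A background of reads from silent genes that is larger in the controls is a candidate explanation for the low genes as a whole, since 1759 olfactory and vomeronasal receptor genes, silent in keratinocytes, lay at 0.59 and 0.37 of the control level per kilobase in libraries 3 and 4. By the median, the lymphocyte markers lay 6.98 times above the receptor genes per kilobase in the controls. This argues against a background of the receptor genes' size as the whole cause of their fall. Its size at other genes was not measured, and only 4 of the 24 markers reached a mean of 5 CPM in the controls. A larger background at these markers therefore stays open. Fewer lymphocytes in the cultures labelled Otub2 knockout could lower these markers. The Cd3 genes lay below both controls in both libraries, as this needs, with 0.837 the highest ratio to the lower control. Cd3e, at 0.692 of the control mean in library 3, was not lower by more than the receptor genes, as the test also asked. This explanation stays open, since low genes of other kinds were lower too.

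The lower ribosomal protein transcripts in both libraries could reflect gene length or reads shared with processed pseudogenes. Removing the trend of fold change on length took 17.4% of the list's distance from genes of mean CPM of at least 5. The distance went from -1.11 to -0.92, which argues against length as the whole cause. Across genes of mean CPM of at least 5, longer genes tended to have higher log2 fold changes (Spearman correlation 0.177). The trend was removed for this list only, so length was not separated from the changes in other lists, families or genes. The 41 ribosomal protein pseudogenes had a median log2 fold change of -0.662, where a shift of reads to them needs a value above 0. No biological explanation was tested, and the Otub2 genotype remains among the open ones, as do differences in growth between the cultures.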
